A study of Paraphaeosphaeria sporulosa with 23 samples.

How the data were processed

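The measurements were RNA sequencing reads per gene from whole cultures of Paraphaeosphaeria sporulosa AP3s5-JAC2a, a filamentous fungus, with or without 0.1 mM sodium selenite. Selenite is an oxyanion of selenium(IV). Per the labels' protocols, homogenised mycelium from a 14-day preculture was grown in still flasks of a yeast extract medium for 18 days before selenite was added, and that moment was day 0. Total RNA was treated with DNase on a column and made into libraries with a stranded kit for messenger RNA. The 23 libraries formed 5 groups by the titles in the labels: 3 controls at day 0, 6 controls and 5 selenite libraries at day 1, and 5 controls and 4 selenite libraries at day 6. The labels give all libraries the same batch. They do not say whether replicates came from separate flasks, so p-values measure the spread between these libraries, part of which may be technical.

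Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.1a, featureCounts of Subread 2.0.6, R 4.1.0 and edgeR 3.36.0. The genome build is not given in the sources used here. The authors made the counts with featureCounts 2.0.6, per the file headers, with strand option 2 and an option for paired reads but none for counting read pairs, so each mate of a pair was counted singly. Counting used strand, so reads of a gene and of an antisense neighbour were kept apart. Among genes with over 200 reads in all libraries together, 55.6% to 70.3% of counts were even in a library. A count of 0 was taken as even, so genes without reads add to this share. Reads counted mate by mate are not independent molecules.

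The deposited count table gave numbers for 13 of its 15164 genes in the form used here, together with the exon positions of all genes, so the measurements came from the deposited table of CPM, the counts scaled to a common library total. That CPM table, made by the authors, divides the reads of each gene by the library's reads in all genes, with no composition factor. Library totals were read from the 13 genes with counts. With those totals, 100% of the 348772 CPM values came out as whole reads within 1e-06 reads, and all 13 genes matched their counts in every library. Totals ran from 23282564 to 32681888 reads, so 1 read was worth 0.0306 to 0.0430 CPM, and 3 reads, the floor taken here for a gene without reads, 0.0918 to 0.129 CPM. Intervals and floors of this kind cover counting error only.

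The deposited tables for day 1 and day 6 hold log2 fold changes, F statistics (a score per gene), p-values and adjusted p-values that the authors computed; the file headers name the columns but no test. The adjusted p-values in both equal a Benjamini-Hochberg adjustment of their p-values. Their genes, 12045 and 12787, are those that edgeR's filterByExpr keeps from the libraries of the compared groups alone. Another table of 4611 genes, deposited by the authors, gives time-course p-values, an R-squared score of at least 0.70, cluster numbers and other identifiers from UniProt for 2713 genes; per the file headers it comes from maSigPro. Its per-library values were in CPM on another total, according to a check of the deposited tables, and were used only in that check. Values in the CPM table were 0.977 to 0.995 times these.

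Genes carry locus tags of the RefSeq annotation (14844 genes) or names beginning with STRG that the authors added (320 genes). The RefSeq gene table of assembly Parsp1 matched 14839 locus tags, 14815 of them with the same start. Its symbols are the locus tags themselves, and the deposited files do not pair genes with product names. The 30 gene lists fixed before the data were examined, and the tests of annotation phrases, needed such names and were not run. Positions below are those in the deposited count table, counted from 1.

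The design written before the data were examined assumed whole counts and named edgeR's quasi-likelihood test. In its place, each comparison was tested by limma 3.58.1 in R 4.3.3, with a trend of variance on level. It used log2(CPM divided by a TMM factor, plus a pseudocount of 0.5). The unit of the values did not force this choice. Whole reads could be recovered from the CPM, and the planned test on them was run as an alternative. TMM factors, the trimmed-mean factors of edgeR 4.0.16, ranged from 0.557 to 1.61. Fold changes are on that log2 scale, which understates changes of genes with few reads. All 23 libraries entered a single fit with 5 group means and no block. The filterByExpr function kept 13676 genes (minimum count 10, minimum total count 15) and left out 1488; kept genes held at least 99.99% of the reads of every library. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, in a two-sided test. The 5 comparisons were selenite against control at day 1 and at day 6, the difference between those changes, and controls at day 1 and at day 6 against day 0. Errors beside log2 fold changes are the standard errors of the limma fit, and errors beside levels are SDs. Levels of genes are in scaled CPM, that is CPM divided by the TMM factor, and shares of reads are of all reads without scaling.

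The rule for named genes was written before the data were examined. For genes without product names it takes at most 2 rises and 2 falls per comparison. These were the largest log2 fold changes among called genes with a mean log2 CPM of at least 1 and, for comparisons of groups, no overlap between the groups' libraries. It gave 18 genes. CC84DRAFT_1180339, the gene with the most reads in most libraries, and the runs of neighbouring genes were chosen after their values were seen.

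The fit was tested on simulated counts with 200 changed genes per comparison. In the real data far more genes were called, 62.5% of those tested for selenite at day 1 and 48.6% at day 6. The adjusted threshold depends on the share of genes that change. The shares below thus describe the simulated setting and do not give the recovery or the false calls of the real comparisons. For selenite at day 1, over 13481 genes, limma recovered 1.49% of 1.5-fold, 35.8% of 2-fold and 65.2% of 4-fold changes, and 2.86% of its calls were false. For day 6, over 13432 genes, it recovered 1.49%, 26.9% and 69.7%, with 4.41% false. For the difference between days, over 13473 genes, it recovered 0%, 2.99% and 37.9%. For controls from day 0 to day 1, over 13454 genes, it recovered 1.49%, 19.4% and 62.1%, with 5.17% false, and for controls from day 0 to day 6, over 13473 genes, 4.48%, 20.9% and 66.7%, with 3.17% false.

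The 44 pairs of replicates were compared by a chi-square of their reads over genes; the smallest value per degree of freedom was 14.9 and the largest 311, so no library was a repeat of another within counting noise. Single measures per library were compared by exact two-sided permutation tests of the difference in means, adjusted by Benjamini-Hochberg over 18 tests. Alternatives tried were the size factors of DESeq2 1.42.0, library size alone, no filter, a filter of 1 CPM in at least 5 libraries (3 where day 0 was compared), the Wald test of DESeq2, limma-voom, a fit of the compared groups alone, other thresholds, a test against a 1.5-fold change, a replicate block and each library left out in turn. Chosen after the data were seen were pseudocounts of 0.1 and 1 and sets of libraries left out together. The planned quasi-likelihood test of edgeR was also run, and its use on the recovered reads and on halved reads was chosen then as well.

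Runs of neighbouring genes were at least 4 consecutive tested genes on a scaffold, all called, in the same direction, with a log2 fold change of at least 2 in size. Their number was compared with 1000 random placements of the genes, also within 10 bins of control level. Near-silent genes for a day had a mean under 0.1 CPM in the controls of the other days. Both definitions were made after the data were seen.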

Results

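Transcript levels of Paraphaeosphaeria sporulosa were measured by RNA sequencing in control cultures at days 0, 1 and 6 and in cultures with 0.1 mM selenite at days 1 and 6. The 23 libraries held 23282564 to 32681888 reads in genes, and 13676 genes entered the tests. Total reads did not separate selenite from control libraries at day 1 (27536477 ± 1582003, SD, n = 5, against 28959876 ± 2709157, n = 6; exact permutation p = 0.348) or at day 6 (29530228 ± 3914823, n = 4, against 27149877 ± 3254552, n = 5; exact permutation p = 0.317). Over the log2 levels of all tested genes, the first principal component held 49.0% of the variance and set the selenite libraries of day 1 (125.7 to 132.2) apart from all controls (−76.1 to −42.3), with the selenite libraries of day 6 between them (33.3 to 76.0). The second component held 15.6%, with the controls of day 1 at 14.9 to 81.2, those of day 0 at −37.1 to 4.37 and those of day 6 at −90.4 to −29.1. The third component held 10.8% and set the selenite libraries of day 6 (−86.7 to −51.8) apart from those of day 1 (26.8 to 50.9). All controls lay at −9.81 to 32.9 on it, so selenite libraries of day 6 were not between the others on every component. The mean correlation between libraries, across genes, was 0.956 to 0.969 within groups, 0.800 between selenite and control at day 1 and 0.832 between them at day 6.

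**Figure D1:**
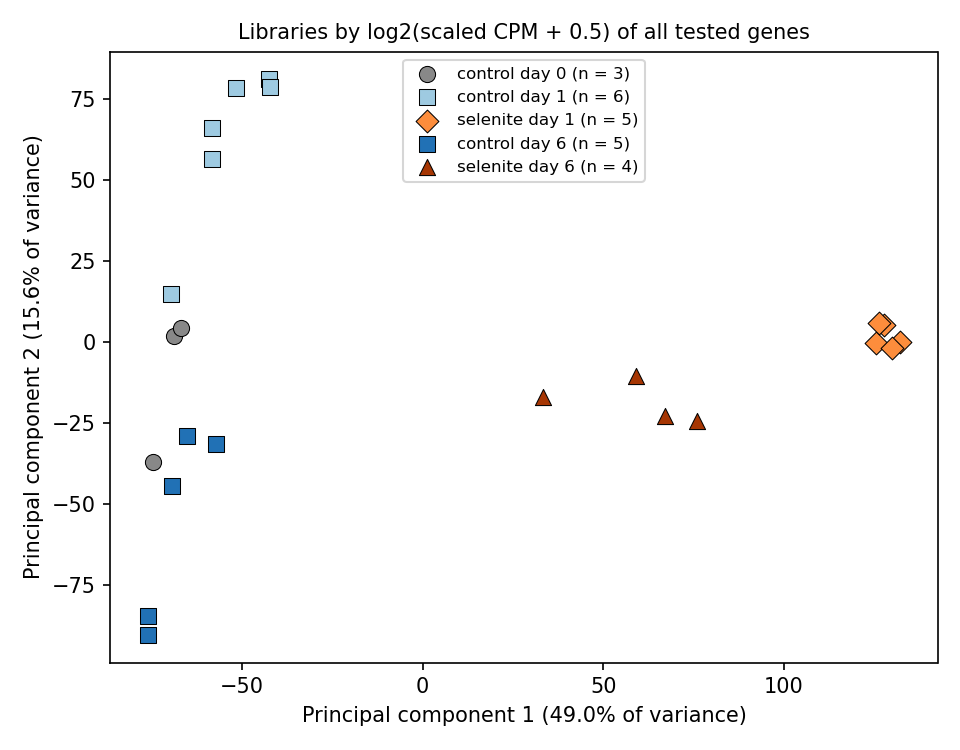
Each point is a library, placed by principal components 1 (49.0% of variance) and 2 (15.6%) of log2(scaled CPM + 0.5) over all tested genes, in component units. The selenite libraries of day 1 lie at 125.7 or above on component 1, those of day 6 at 33.3 to 76.0, and all controls at −42.3 or below; control day 1 replicate 1 lies at 14.9 on component 2.

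After 1 day of selenite the rule for named genes gave as rises CC84DRAFT_1222313 and CC84DRAFT_1208187. CC84DRAFT_1222313, a gene of 3 exons on the minus strand of scaffold NW_017253372.1 (313545 to 315382), rose from 0.95 ± 0.91 scaled CPM in controls (SD, n = 6) to 4561 ± 323 with selenite (n = 5). Its log2 fold change was 11.86 ± 0.43 (SE). CC84DRAFT_1208187, a gene of 1 exon on the minus strand of NW_017253368.1 (573536 to 574441), rose from 0.50 ± 0.74 to 3117 ± 748 scaled CPM, a log2 fold change of 11.84 ± 0.44. With controls this low the order of the genes turned with the processing: over the alternatives the values were 11.30 to 13.22 for the former and 11.11 to 14.23 for the latter, and the authors' deposited table has 12.27 and 12.69. The named falls were CC84DRAFT_1239841 and CC84DRAFT_1162499, which lie near each other on NW_017253362.1 (1995940 to 1997122, minus strand, and 1999991 to 2001314, plus strand). Against controls of the same day, the former fell by 7.16 ± 0.46 on the log2 scale, from 275 ± 105 to 1.81 ± 1.67 scaled CPM. The latter fell by 6.35 ± 0.28, from 214 ± 79.4 to 2.21 ± 1.27. Both had risen in controls since day 0, when they had 7.88 ± 3.14 and 86.0 ± 35.1 (n = 3). These control changes were 5.02 ± 0.53 and 1.29 ± 0.33 (limma adjusted p 1.75e-07 and 0.00466). The adjusted p-values from limma were 4.36e-17 and 5.16e-17 for the rises and 9.81e-13 and 1.57e-15 for the falls.

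Genes that rose at least 8-fold at day 1, 760 in number, took 14.9% ± 0.87 of the reads in selenite libraries (SD, n = 5) and 0.647% ± 0.037 in controls of the same day (n = 6). The 223 genes that fell at least 8-fold took 0.437% ± 0.060 of the reads with selenite and 7.16% ± 0.56 without. These genes were chosen by the same comparison, so the shares describe the size of the change and do not test it. CC84DRAFT_1191218 on NW_017253374.1 (246500 to 247631), named by its change in the controls, had 18196 ± 2379 scaled CPM with selenite and 143 ± 55.5 without, a log2 fold change of 7.09 ± 0.69 (limma adjusted p 2.45e-09). The gene with the most reads in every library of day 1 was CC84DRAFT_1180339, a gene of 1 exon on NW_017253371.1 (86589 to 87170). It held 10.98% ± 1.51 of all reads with selenite and 5.74% ± 1.02 without; all 5 selenite libraries lay above all 6 controls (exact permutation p = 0.00216, the smallest that 462 splits can give; 0.00974 adjusted over 18 tests). In the fit across genes its log2 fold change of 1.36 ± 0.99 did not pass the threshold (limma adjusted p 0.239), while the authors' deposited table gives 1.46 with an adjusted p of 3.58e-05. The error in the fit is shared by all 5 groups. It takes in the day 6 controls, with 24763 ± 23614 scaled CPM of this gene (SD, n = 5). At day 1 the levels were 178653 ± 39381 with selenite and 69492 ± 15548 without. The 100 genes with the most reads in each library together held 57.6% ± 3.79 of reads with selenite and 41.2% ± 2.83 without (exact permutation p = 0.00216, adjusted 0.00974).

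In all, 8554 of 13676 genes were called at day 1 by limma, 4215 higher and 4339 lower with selenite, and 6333 of them changed at least 2-fold (3310 higher, 3023 lower). For 5733 of the called genes the selenite and control libraries did not overlap; over all tested genes the share without overlap was 42.1%, against 0.433% by chance. The direction split depended on scaling: 49.3% of called genes were higher with TMM factors, 55.3% with DESeq2 size factors, and with library size alone 3146 were higher and 5356 lower. These scalings moved the median change of all genes by 0.14 and −0.28 on the log2 scale. Tested against a 1.5-fold change in place of none, 5318 genes were called.

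**Figure D2:**
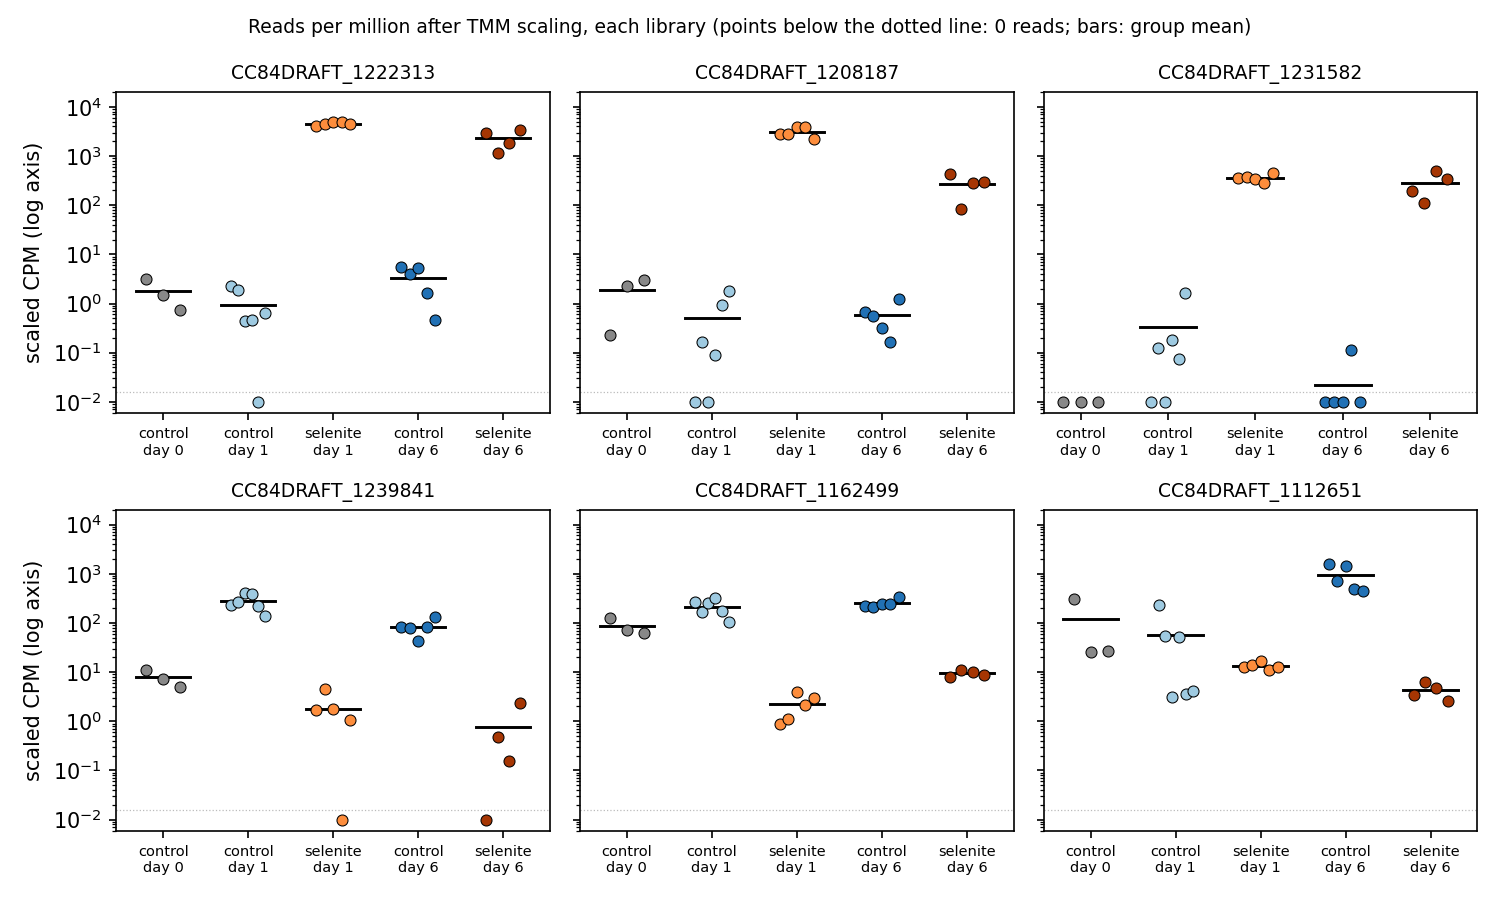
Scaled CPM (log axis) of 6 named genes in each library, by group, with bars at group means; points below the dotted line are libraries with 0 reads. CC84DRAFT_1222313 has a mean of 4561 with selenite and 0.95 in controls at day 1, and 2321 and 3.35 at day 6, while CC84DRAFT_1112651 has means of 13.4 and 57.8 at day 1 and 4.25 and 927 at day 6.

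After 6 days CC84DRAFT_1222313 was again a named rise, with 2321 ± 1010 scaled CPM with selenite (SD, n = 4) against 3.35 ± 2.23 in controls (n = 5), a log2 fold change of 9.41 ± 0.48 (SE). CC84DRAFT_1231582, a gene of 4 exons on the same scaffold (NW_017253372.1, 650301 to 651971, minus strand), reached 283 ± 168 scaled CPM, while the controls of day 6 held 4 reads in all, in 1 of 5 libraries. Its log2 fold change of 8.87 ± 0.39 rests on the pseudocount and ranged from 7.90 to 13.66 over the alternatives, against 8.98 to 9.95 for CC84DRAFT_1222313, so their order was not fixed either; the authors' deposited table has 13.54 and 9.42. CC84DRAFT_1227985, of 3 exons on NW_017253360.1 (5136406 to 5138171, minus strand), fell by 8.84 ± 1.07, from 454 ± 138 to 0.467 ± 0.196 scaled CPM. CC84DRAFT_1112651, of 6 exons on NW_017253361.1 (3237199 to 3239599, minus strand), fell by 7.48 ± 0.89, from 927 ± 518 to 4.25 ± 1.58. In controls it had risen from 119 ± 161 at day 0 (n = 3), a log2 change of 3.76 ± 0.97 (limma adjusted p 0.00802). Control day 6 replicates 1 and 3 had 1545 and 1417 scaled CPM of it and the other 3 had 452 to 726, and without those 2 its log2 change was −6.94. The adjusted p-values from limma were 7.75e-14 and 3.2e-15 for the rises and 2.22e-07 and 1.93e-07 for the falls. The 347 genes that rose at least 8-fold, chosen by this comparison, held 9.04% ± 1.18 of reads with selenite and 0.591% ± 0.227 in controls, and the 309 that fell as much held 0.572% ± 0.109 and 10.0% ± 2.85.

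Selenite libraries of day 6 had fewer genes without any read than controls, 1365 ± 218 (SD, n = 4) against 2348 ± 324 (n = 5; exact permutation p = 0.0159, adjusted 0.0357 over 18 tests). At day 1 these numbers were 2397 ± 327 with selenite (n = 5) and 2783 ± 258 in controls (n = 6), and the difference did not pass (exact permutation p = 0.0584, adjusted 0.0877). Genes at 1 CPM or more were more numerous with selenite on both days. The difference passed at day 1 (10591 ± 188 against 10134 ± 216; exact permutation p = 0.0108, adjusted 0.0325) and not at day 6 (11589 ± 224 against 11257 ± 123; exact permutation p = 0.0317, adjusted 0.0635). The top 100 genes held 29.8% ± 3.79 and 27.8% ± 3.23 of the reads at day 6 (exact permutation p = 0.397, adjusted 0.420). In all, 6643 genes were called by limma at day 6, 3698 higher and 2945 lower, of which 4736 changed at least 2-fold (2587 higher, 2149 lower). The majority direction turned with library size alone, which gave 3234 higher and 3504 lower (median shift −0.14); the higher share was 55.7% with TMM factors and 53.0% with DESeq2 size factors. The groups did not overlap for 4905 of the called genes, and for 38.3% of all tested genes against 1.59% by chance. Control day 6 replicates 1 and 3 lay at −90.4 and −84.7 on the second component, below the other controls of that day (−44.4 to −29.1). With a test against a 1.5-fold change 3189 genes were called.

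Most genes that changed on both days kept their direction. Of the 10552 genes called on either day, 2124 were higher with selenite on both (1140 expected for independent lists) and 1703 lower on both (934 expected), while 270 were higher at day 1 and lower at day 6 (908 expected) and 548 the reverse (1173 expected). The 2 comparisons share no library. Across genes, which are not independent replicates, the log2 fold changes of the days had a Pearson correlation of 0.560 and a Spearman correlation of 0.495. Of the 6333 genes changed at least 2-fold at day 1, 76.7% had the same sign at day 6. By the test of the difference, 3448 (54.4%) had a smaller or reversed change at day 6, and 245 had a larger one in the same direction. At day 6, 497 of the 6333 were called in the opposite direction. Of the 4736 chosen in the same way at day 6, 79.3% had the same sign at day 1. A smaller or reversed change at day 1 was found for 1743 (36.8%), and a larger one in the same direction for 678. At day 1, 432 of the 4736 were called in the opposite direction. Genes chosen for a large change on a day tend to show a smaller one on another, and both choices carry this bias. CC84DRAFT_1222313 and CC84DRAFT_1208187 rose less at day 6, by differences of −2.45 ± 0.65 and −4.00 ± 0.66 (limma adjusted p 0.00348 and 2.89e-05).

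**Figure D3:**
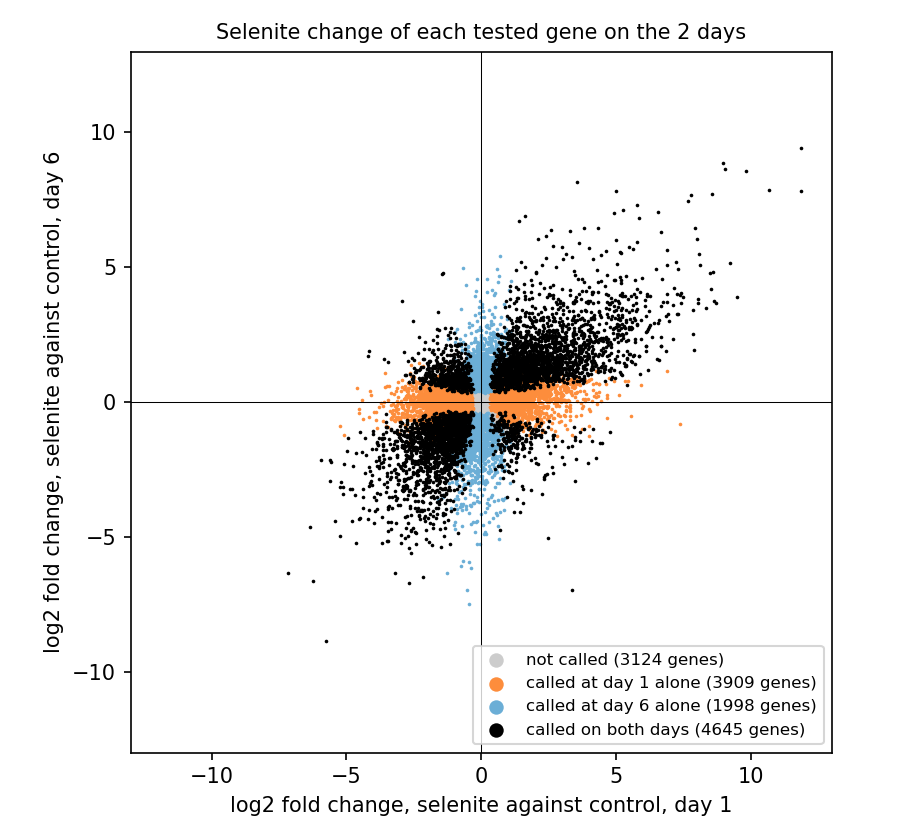
Each point is a tested gene, with its log2 fold change of selenite against control at day 1 (horizontal) and at day 6 (vertical), coloured by the days on which it was called. Genes called on both days lie mostly in the quadrants of equal sign (2124 higher and 1703 lower on both days), and 818 lie in the other quadrants.

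The selenite change differed between days for 5930 genes, in the positive direction for 3098 and the negative for 2832. CC84DRAFT_238584, of 2 exons on NW_017253369.1 (1335909 to 1336733, plus strand), fell by 2.95 ± 0.65 at day 1, from 546 ± 178 to 69.1 ± 22.5 scaled CPM, and rose by 3.75 ± 0.72 at day 6, from 70.7 ± 63.0 to 606 ± 170. CC84DRAFT_1219326, of 2 exons on NW_017253366.1 (1909985 to 1912323, plus strand), likewise fell at day 1 (−1.43 ± 0.53) and rose at day 6 (4.77 ± 0.58). CC84DRAFT_1138657, of 3 exons on NW_017253361.1 (2845729 to 2847183, minus strand), rose at day 1, from 1.88 ± 1.82 to 17.7 ± 4.06 scaled CPM, and fell at day 6, from 583 ± 381 to 3.90 ± 2.63. CC84DRAFT_1131304, of 4 exons on NW_017253374.1 (649153 to 651496, minus strand), rose at day 1 by 7.38 ± 0.43, from 2.49 ± 1.27 to 489 ± 223 scaled CPM, and at day 6 had 23.1 ± 7.50 with selenite and 47.4 ± 32.4 without, which did not pass (limma adjusted p 0.159). Control day 6 replicates 1 and 3 raised the control means of both genes, with 855 and 1118 scaled CPM of CC84DRAFT_1138657 (268 to 337 in the other 3) and 90.7 and 73.3 of CC84DRAFT_1131304 (20.2 to 30.2). The differences were 6.70, 6.20, −10.33 and −8.20 (limma adjusted p 5.88e-06, 1.06e-06, 3.19e-09 and 2.06e-09). Without these 2 libraries the last 2 were −9.76 and −7.63. All 818 genes called in opposite directions on the 2 days also passed the test of the difference, and 292 of them changed at least 2-fold on both. The positive share of the 5930 differences was 52.2% with TMM factors, 41.9% with DESeq2 size factors and 63.3% with library size alone, whose median shifts were −0.18 and 0.19, and 3079 genes passed a test against a 1.5-fold difference.

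Control cultures also changed with time in the absence of selenite. From day 0 to day 1, CC84DRAFT_1207412 on NW_017253366.1 (2319233 to 2320776) rose by 6.62 ± 0.51 on the log2 scale (SE), from 0.138 ± 0.238 scaled CPM (SD, n = 3) to 62.4 ± 20.1 (n = 6). The day 0 controls held 12 reads of it, in 1 of 3 libraries. Its fold thus rests on the pseudocount and ranged from 5.75 to 10.51 over the alternatives. CC84DRAFT_1203498 on NW_017253362.1 (573261 to 575820) rose by 6.33 ± 0.38, from 23.8 ± 12.9 to 1860 ± 514. Control day 0 replicate 1 stood apart from the other 2 libraries of its day, at −37.1 on the second component against 1.77 and 4.37. CC84DRAFT_1138657 fell by 5.33 ± 0.65, from 116 ± 141 (279 in that library, 39.6 and 30.2 in the others) to 1.88 ± 1.82. Without that library its log2 change was −4.32. CC84DRAFT_1258095 on NW_017253363.1 (807913 to 809917) had a log2 change of −3.83 ± 0.42, from 215 ± 45.8 to 18.0 ± 14.3. The adjusted p-values from limma were 1.45e-09, 4.73e-11, 1.5e-06 and 2.75e-07. From day 0 to day 6, CC84DRAFT_1191218 rose by 3.88 ± 0.84, though control day 6 replicates 1 and 3 had 4.91 and 6.99 scaled CPM and the other 3 controls 175 to 203. This call was lost with limma-voom (4.06, adjusted p 0.102). CC84DRAFT_1159994 on NW_017253360.1 (4251969 to 4252990) rose by 3.80 ± 0.62, from 6.33 ± 6.80 to 78.9 ± 48.9 (n = 5). Control day 0 replicate 1 had 14.1 scaled CPM of it and the other 2 had 1.66 and 3.20, while control day 6 replicates 1 and 3 had 118 and 144 and the other 3 had 35.4 to 51.2. Its log2 change was 4.59 without the former library and 3.20 without the latter 2. CC84DRAFT_1153079 on NW_017253369.1 (168643 to 170260) fell by 4.99 ± 0.70, from 113 ± 91.9 to 1.86 ± 0.83, and CC84DRAFT_166891 on NW_017253360.1 (4811936 to 4812767) fell by 4.88 ± 0.76, from 360 ± 317 to 8.09 ± 6.20. Control day 0 replicate 1 had 535 and 1058 reads of these, against 3965 to 6005 and 12593 to 19023 in the other 2. Without it the log2 changes were −6.21 and −6.34. The 4 genes named for day 6 had limma adjusted p-values of 0.00233, 0.000222, 5.56e-05 and 0.000138.

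By limma, 3802 genes changed in controls between days 0 and 1 (2053 higher, 1749 lower) and 2891 between days 0 and 6 (1330 higher, 1561 lower). The groups did not overlap for 3039 and 2230 of these genes; over all tested genes 26.8% and 25.2% showed no overlap, against 2.38% and 3.57% by chance. Of the genes changed on either day, 471 were higher and 443 lower at both, against 200 each for independent lists, and 133 changed in opposite directions. These comparisons share the day 0 libraries: the covariance of log2 fold changes across genes was 0.231, against 0.0999 simulated for shared libraries with no effect, and the 3 libraries could not be split into parts of 2. The correlation was 0.301, and 0.648 in the simulation without effects. The direction split moved with scaling here too. The higher share from day 0 to day 1 was 54.0% with TMM factors and 19.5% with library size alone (median shift −0.40), and from day 0 to day 6 it was 46.0% and 73.4% (median shift 0.22). Without control day 0 replicate 2 or 3 the number of genes from day 0 to day 6 was 1238 or 1177, and without control day 6 replicates 1 and 3 together it was 1498.

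Genes that were near silent in the controls of other days gained reads with selenite. At day 1 the 2019 such genes summed to 1902 ± 132 CPM with selenite (SD, n = 5) and 70.4 ± 9.20 in controls (n = 6; exact permutation p = 0.00216, the smallest possible). Of these genes 211 reached a mean of 1 CPM with selenite against 5 in controls, and 109 reached it in every selenite library against 1 in every control library, while 829 had no read in any selenite library. At day 6 the 2320 such genes summed to 1427 ± 555 CPM (n = 4) against 195 ± 39.6 (n = 5; exact permutation p = 0.00794, the smallest possible), with 223 against 14 at a mean of 1 CPM and 74 against 0 in every library. Among 1883 genes near silent by both definitions, 176 reached 1 CPM with selenite at day 1 and 136 at day 6. Both lists shared 95 genes, against 12.7 for independent lists.

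A small part of the changed genes lay side by side on the scaffolds. At day 1 there were 28 runs of at least 4 neighbouring genes that all changed at least 4-fold in the same direction, 22 of them higher and 6 lower with selenite, with 117 genes on 13 scaffolds and spans of 3.35 to 17.8 kb. Random placement of the genes gave a mean of 2.26 runs and a highest number of 7, and placement within 10 bins of control level a mean of 3.18 (permutation p = 0.001 for both, the smallest that 1000 draws can give). A run of 5 genes on NW_017253363.1 (1883155 to 1891093, from CC84DRAFT_1163467 to CC84DRAFT_1163471) summed to 3016 ± 697 scaled CPM with selenite (SD, n = 5) and 70.9 ± 11.6 in controls (n = 6), with a median log2 fold change of 5.72 at day 1 and 3.37 at day 6. CC84DRAFT_1222313 lay in a run of 4 genes (NW_017253372.1, 309664 to 317651) whose median rose by 5.87 at day 1 and 4.71 at day 6. CC84DRAFT_1239841 and CC84DRAFT_1162499 lay in a run of 4 genes (NW_017253362.1, 1995940 to 2003530) whose median log2 change was −6.29 at day 1 and −5.49 at day 6. The 22 higher and 6 lower runs of day 1 all had a median of the same sign at day 6, where 96 of the 117 genes were called in the same direction. Of all genes changed at least 2-fold at day 1, 49.3% were called in the same direction at day 6. Genes outside runs with 4-fold changes were not counted, so this persistence cannot be called particular to the runs. At day 6 there were 6 runs, 3 higher and 3 lower, against a mean of 0.362 by random placement (permutation p = 0.001), and 3 of them were also runs at day 1.

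**Figure D4:**
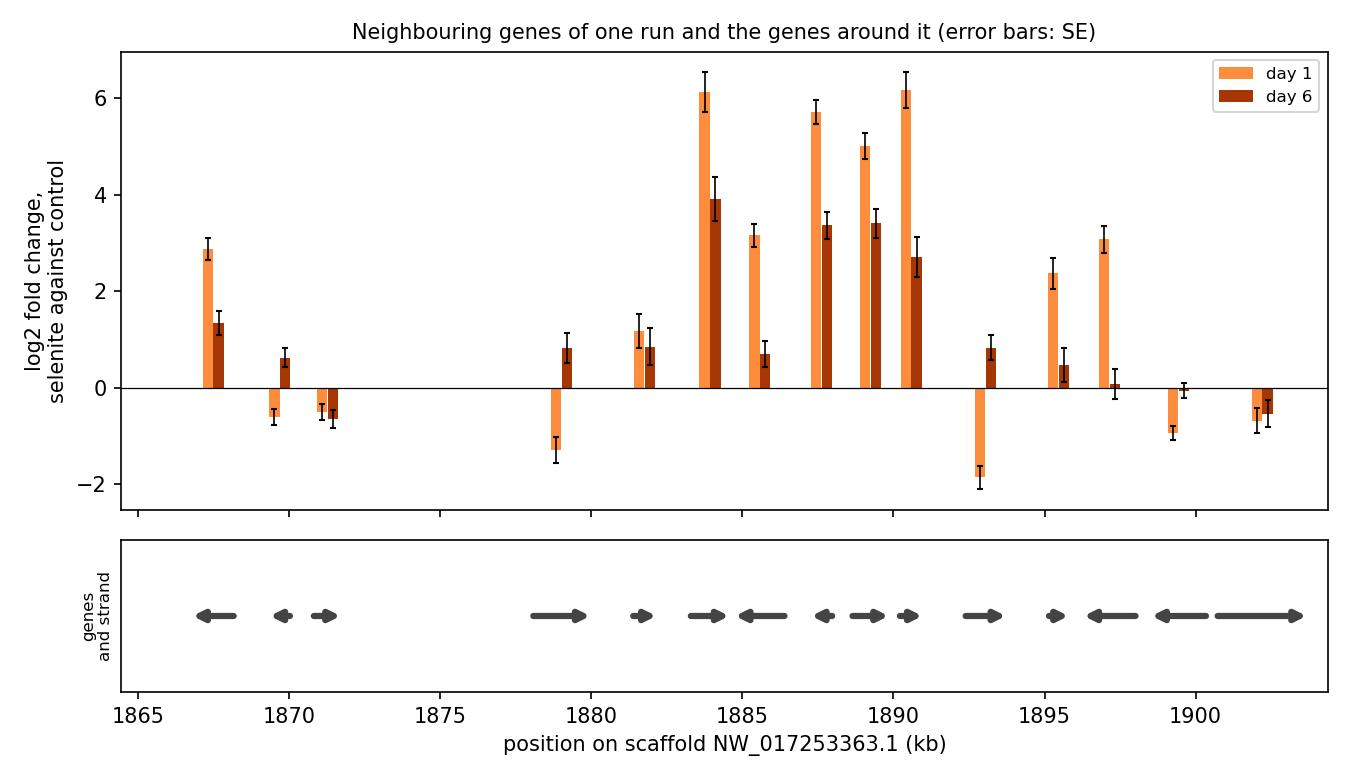
Log2 fold changes of selenite against control at day 1 and day 6 (bars, with SE) for neighbouring genes on scaffold NW_017253363.1, placed by position in kb, with arrows for gene extent and strand. The 5 genes from 1883155 to 1891093 changed by 3.16 to 6.17 at day 1, the gene before the run, CC84DRAFT_1088876, rose by 1.18, and the genes after it include a fall of 1.86 at CC84DRAFT_1175105 and a rise of 3.07 at CC84DRAFT_1258420.

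The authors' deposited tables call 7326 of 12045 genes at day 1 (3668 higher, 3658 lower) and 6086 of 12787 at day 6 (3127 higher, 2959 lower). Of these, 7089 and 5741 were called here by limma in the same direction and 0 in the opposite one; 237 and 345 were called only in the authors' deposited tables, and 926 and 756 of the genes in those tables only here. In the authors' deposited table CC84DRAFT_1222313 has log2 fold changes of 12.27 at day 1 and 9.42 at day 6. The 4611 genes of the authors' deposited time-course table, which were chosen on these same libraries and so are no independent evidence of direction, are grouped there in several ways, into 5 to 9 clusters. The grouping into 5, the coarsest, was chosen after the table was seen. The others were not used here. Cluster 2, of 1740 genes, had median log2 fold changes of 1.39 at day 1 and 0.78 at day 6, with 1466 and 1034 genes called higher and 20 and 167 lower. Cluster 1, of 403 genes, had medians of 0.60 and 1.51, with 211 and 352 called higher and 42 and 0 lower. Cluster 3, of 1042 genes, was lower on both days (−1.26 and −1.32, with 820 and 897 called lower and 59 and 4 higher). Clusters 4 and 5, of 599 and 827 genes, were lower at day 1 (−1.67 and −1.51, with 577 and 734 called lower and 0 and 22 higher). At day 6 they had medians of −0.21 and −0.05, with 130 and 167 genes called higher and 227 and 229 lower. The signs of these medians were the same with DESeq2 size factors and with library size alone, but the sizes moved. With library size alone the median of cluster 1 at day 1 was 0.18 (146 higher, 82 lower), and at day 6 those of clusters 4 and 5 were −0.40 and −0.23; with DESeq2 size factors that of cluster 5 was −0.11.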

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

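The counts over other splits of the libraries, the tests on near-silent genes and the random placement of runs were chosen after the results were seen; the tests on strand and on abundant genes were set before theirs.

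The change with selenite differed between days, by the limma test of the difference, for 5930 genes and for 13 of the 18 named ones. CC84DRAFT_238584, CC84DRAFT_1219326, CC84DRAFT_1138657 and CC84DRAFT_1131304 were named by this same test, so the number of named genes is no separate evidence. The change at day 6 minus that at day 1, in log2 units, was −10.33 for CC84DRAFT_1138657, −8.20 for CC84DRAFT_1131304 and −7.03 for CC84DRAFT_1112651. It was −4.97 for CC84DRAFT_1159994, −4.90 for CC84DRAFT_1258095, −4.00 for CC84DRAFT_1208187, −3.48 for CC84DRAFT_1191218 and −2.45 for CC84DRAFT_1222313. In the other direction it was 6.70 for CC84DRAFT_238584, 6.20 for CC84DRAFT_1219326, 3.61 for CC84DRAFT_1153079, 2.97 for CC84DRAFT_1207412 and 1.71 for CC84DRAFT_1162499, the last with a fall on both days that was smaller at day 6.

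A library lay far from the others of its group in 11 of 108 groups of values tested. For normally distributed values chance alone gives about 1 in 20 groups (5.4 here). Of the 108 groups, 76 were unlogged levels of named genes, which need not be distributed so, and 5.4 is only a rough guide. Among the 11, 5 were in control day 1 replicate 1. That library had 14.9 on the second principal component (56.6 to 81.2 in the other 5 controls of the day) and, in scaled CPM, 4189 for CC84DRAFT_1227985 (at most 1356), 232 for CC84DRAFT_1112651 (3.16 to 53.1), 45.7 for CC84DRAFT_1258095 (5.59 to 17.1) and 49.0 for CC84DRAFT_1159994 (3.78 to 11.7). Control day 1 replicate 2 had 63.4 scaled CPM of CC84DRAFT_1153079 (5.26 to 19.3) and 20.5 of CC84DRAFT_166891 (35.8 to 44.3), and control day 1 replicate 6 had 1.61 of CC84DRAFT_1231582 (0 to 0.181). Control day 6 replicate 1 had 0.397 scaled CPM of CC84DRAFT_1153079 (2.08 to 2.44), replicate 4 had 0.111 of CC84DRAFT_1231582 (0 in the other 4), and replicate 5 had 332 of CC84DRAFT_1162499 (208 to 241).

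Other splits of the same libraries gave as many genes in 1 of 100 splits at day 1, the real one (8554 genes; the highest other split gave 7324), in 1 of 100 at day 6 (6643; 5367), in 1 of all 84 for controls from day 0 to day 1 (3802; 376) and in 1 of all 56 from day 0 to day 6 (2891; 1311). The median of the other splits was 0 genes in each case, and the highest at days 1 and 6 kept 1 of 11 and 1 of 9 libraries in their groups, so they were near exchanges of the labels. For these 4 counts the share of splits was under 0.05, which argues against chance assignment only if the libraries are independent replicates. Some libraries lay closer to each other than to the rest of their group. For control day 0 replicates 2 and 3 the chi-square per degree of freedom was 15.3, against 249 and 286 with replicate 1. Whether libraries shared a flask is not known, and the splits cannot exclude such grouping. For the difference between days 2 of 100 splits gave as many genes (5930 in the real one), and the other, with 6959, left all 11 libraries of day 1 in their groups and 3 of the 9 of day 6, so that most day 6 labels were exchanged. Splits within days also take away the selenite change itself, so for this count they do not show whether the change differed between days.

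Near-silent genes with reads in selenite libraries were the first pattern weighed. Genomic DNA in the selenite libraries would spread reads by gene length, but the tenth of these genes with the most reads per kb held at least 85.9% of their reads in every selenite library at day 1 and 68.8% at day 6, against at most 10.4% and 10.6% in a simulation by length. This argues against genomic DNA as the main source of the summed reads. A low level of it over the remaining genes was not tested, because the sum follows the genes with most reads. Greater depth is also argued against, since the reads in these genes were at least 21.2 times as many in a selenite as in a control library at day 1 and 4.87 times at day 6, while library totals differed by at most 1.14 times at day 1 and under 1.5 times at day 6 in that direction. Reads shared between similar gene copies could not be examined without a genome sequence and stay open. A response of these genes to selenite, the treatment in the design, stays open beside it as a hypothesis.

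Runs of neighbouring genes that changed together at day 1 were the second pattern. Chance placement is argued against, since no more than 10 runs arose in any of 1000 placements within bins of control level, against 28. Transcription running on from a gene into the next may account for part of the runs: 34.8% of neighbouring pairs in runs lie on opposite strands, against 53.1% of all neighbours, and this value, between the bounds set beforehand, leaves the explanation undecided. It cannot be told apart from shared regulation for pairs on the same strand, while 20 of the 28 runs hold genes of both strands. Reads shared between adjacent similar copies were not tested.

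The share of higher calls at day 1, which moved with the scaling, was the third pattern. A few genes taking most of the reads is a candidate explanation: leaving the 100 genes with the highest mean CPM out of the library totals moved the median log2 change of the other genes by 0.31, from −0.31 to 0.00, against −0.02 with TMM factors. With those totals 50.3% of called genes were higher. The same step came less close to the TMM medians in the other comparisons. It moved the median by 0.02 at day 6 and by −0.33 for the difference between days. For controls at days 1 and 6 against day 0 it moved it by 0.19 and −0.01. The medians with TMM factors then lay 0.12, 0.14, 0.21 and −0.21 away, in the same order. A change in the total amount of messenger RNA per cell is not measured by any of these scalings, so no direction of the whole transcriptome can be read from the split.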

How the results depend on the processing

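The edgeR tests on recovered and halved reads, the pseudocounts of 0.1 and 1, the sets of libraries left out together and, for genes called on both days, leaving out each library were chosen after the data were seen. Over 161 alternatives for the counts of genes, 150 stayed within 1.5 times, and of 504 values for named genes under alternatives 503 kept their direction and their side of the threshold; CC84DRAFT_1191218 in controls at day 6 against day 0 lost its call under limma-voom (4.06, adjusted p 0.102; 1.9e-11 to 0.102 over its alternatives). Named genes were picked for large changes in the same comparison in which the alternatives were tried, so their stability was favoured by the choice. The 503 of 504 values thus do not describe called genes in general. A test against a 1.5-fold change gave 5318 genes at day 1, 3189 at day 6 and 3079 for the difference. It gave 1087 for controls at day 1 against day 0 and 332 at day 6 against day 0. With an adjusted p under 0.01 the control counts were 2319 and 1319, and with a 2-fold limit the second was 1827; all these calls are stricter by construction. Leaving out control day 6 replicates 1 and 3 gave 1498 genes there, and leaving out control day 0 replicate 2 or 3 gave 1238 or 1177; fewer libraries entered these fits, and the cause was not tested further. With each library left out in turn the counts ran from 8167 to 8512 at day 1, 5863 to 6508 at day 6, 5291 to 6302 for the difference, 2845 to 4024 and 1177 to 3055 for the controls, and 3431 to 3843 for genes called in the same direction on both days. The edgeR quasi-likelihood test on recovered reads called 8272, 6169, 4986, 3565 and 2610 genes in the same order.

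Whether replicate numbers pair the libraries could not be settled with 3 to 5 numbers per comparison. Correlations of same-numbered libraries' deviations were −0.0168 to 0.0220 at day 1 and −0.00776 to 0.0914 at day 6. They were 0.0189 to 0.331 between controls of days 0 and 1, and −0.208 to 0.331 between those of days 0 and 6. Replicate 1 gave both values of 0.331. A library correlated best with its own number in 1 of 5, 2 of 4, 2 of 3 and 2 of 3 cases. With a replicate block the counts were 8486, 6818, 5913, 3678 and 3467, all within 1.5 times. The gene list tests and their alternatives were not run, for want of product names. Depth limits genes near 3 reads, 0.0918 to 0.129 CPM, where a fold change depends on the pseudocount.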

Other observations

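The test of the control profile and that of scaffold ends were set before their results were seen; the measures of gene classes were chosen after the data were examined.

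The summed reads of tRNA genes were higher with selenite at day 1, while most of these genes were not called. The libraries were made with a kit for messenger RNA, and the source of these reads was not examined. The sums thus need not follow tRNA levels. The 104 tRNA genes summed to 72.3 ± 8.28 CPM (SD, n = 5) against 33.3 ± 4.80 in controls (n = 6; exact permutation p = 0.00216, 0.00433 adjusted over 4 tests), and with TMM factors to 116 ± 15.6 against 39.9 ± 4.50. Of the 62 tRNA genes tested singly by limma, 16 were higher and 2 lower, with a median log2 change of 0.05. At day 6 the sums were 55.1 (n = 4) and 87.6 CPM (n = 5), which did not pass (exact permutation p = 0.111, adjusted 0.148), and with TMM factors 42.9 ± 9.84 and 61.3 ± 26.2 (exact permutation p = 0.183). Gene models added by the authors under STRG names held, without scaling, 0.587% ± 0.037 of reads with selenite at day 1 against 1.19% ± 0.128 in controls (exact permutation p = 0.00216, adjusted 0.00433), and 0.965% ± 0.116 against 1.05% ± 0.333 at day 6 (exact permutation p = 0.571). The count of models went the other way at day 1: of 278 tested by limma with TMM factors, 98 were higher and 56 lower, with a median log2 change of 0.25.

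In control day 6 replicates 1 and 3, CC84DRAFT_1180339 had 584 and 1762 scaled CPM, against 25844 to 52970 in the other 3 controls of that day. The share of even counts among genes with over 200 reads in all libraries together was 57.7% ± 2.71 with selenite at day 6 (SD, n = 4). It was 65.5% ± 2.98 in controls (n = 5, exact permutation p = 0.00794, 0.0286 adjusted over 18 tests). At day 1 the shares were 65.7% ± 2.51 and 67.8% ± 1.97 (exact permutation p = 0.143, adjusted 0.198). A count of 0 was taken as even, so genes without reads raise the share. Over all genes, those without reads were fewer with selenite at day 6 (1365 ± 218 against 2348 ± 324). The difference in even counts is thus not separate from that one, and the shares were not compared without counts of 0.

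A hypothesis was that selenite libraries of day 6 kept part of the control profile of day 1. The selenite change at day 6 was compared, across genes, with the level in controls at day 1 minus that at day 6, with the day 6 controls split into parts of 3 and 2 so that no library was shared. The correlation was 0.245 to 0.401 over the 10 splits, with a median of 0.379. Both changes subtract the level in controls at day 6, so a positive correlation is also expected where nothing of the day 1 profile was kept. The test decides nothing, and the hypothesis stays open.

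Another hypothesis, that near-silent genes that rose at day 1 lie near scaffold ends, was not borne out. The 211 risen genes lay at a median of 634 kb from the nearest end of the annotated scaffold and the other 1808 at 517 kb, a difference in the opposite direction (permutation p = 0.0446, two-sided, 10000 permutations).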
